A study of Homo sapiens with 20 samples.

How the data were processed

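Per the labels' protocols, mDCs and monocytes of healthy volunteers were sorted by flow cytometry, and RNA was extracted with a column kit or, at low cell yield, with a kit for small samples. The kit used for each sample is not given in the sources used here. RNA was amplified in a double-cycle biotin labelling procedure and hybridised to short-oligonucleotide arrays of a 2-array set, per the labels. Groups came from the labels: mDCs and monocytes on array A and on array B, with 5 arrays each and 20 in all.

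The deposited values are intensity values on a linear scale, 1 per probe set and array, as the authors made them. The values themselves show that the authors had scaled each array to a common mean: after leaving out 2% of the probe sets at either end, the array means lay between 500.18 and 500.24, while the medians differed. They were neither log-transformed nor quantile normalized. The software and any background correction are not given in the sources used here. No columns remained unmapped, no 2 arrays were identical, and the highest correlation between arrays was 0.993 on array A and 0.980 on array B.

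Array A held 22283 and array B 22645 probe sets, with 68 controls on each. GEO's platform annotation gave 1 gene symbol for 19065 probe sets of array A and 15426 of array B, several for 1043 and 554, and none for 2107 and 6597. Symbols were checked through Entrez identifiers against a current gene table, which held 19053 and 15401 of them and changed none. Probe sets with several genes were tested but not named, except in counts of immunoglobulin probe sets. Control probe sets, and 52 and 33 probe sets of sex-linked genes kept out for the donors' privacy, were left out of everything. No genome build is given, so no coordinates are stated.

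Values were raised to a floor at the pooled 20th percentile of the array type (29.68 on array A and 46 on array B) and log2-transformed. A probe set was tested if at least 5 of the 10 arrays exceeded the pooled median (149.4 and 209.1), which kept 10953 and 11259. A log2 difference is the mDC mean minus the monocyte mean, so the floor understates the difference of dim probe sets, and a group with all arrays at the floor gives a lower bound. Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend), with 5 arrays per cell type and no donor term, and Benjamini-Hochberg adjustment at 0.05 within each array type. Adjusted p-values of single genes are from this limma fit, and SE is that of the moderated difference.

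Gene lists were fixed from knowledge of blood myeloid cells. There were 29 of them, of which 23 had at least 5 measured genes on array A and were tested with limma's camera at its preset correlation between genes. Each gene was represented by the probe set with the highest mean. The 6 others are given as counts. Named genes followed a rule: the 15 genes with the largest difference per direction on array A and the 8 on array B, each called and with the same sign in all 5 donor pairs, up to 4 called members of each list with the largest difference, and the sort markers. Immunoglobulin segments were kept out of that rule. Lists, rule, tests and most alternatives were set before the data were examined. Other genes and list members that stand in the text were chosen after their values were seen. Principal components were computed on centred values of the tested probe sets.

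Both cell types came from the same donors, per the labels, so that the donor numbers pair the samples. The mean correlation of paired deviations from the group means was 0.162 on array A and 0.0683 on array B, and the consensus correlation 0.198 and 0.0989, both without HLA, immunoglobulin and sex-linked probe sets. A donor block was fitted as an alternative.

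The steps were tested on simulated data. Of 100 array A probe sets of 10953 given a log2 change of 1, 40% were recovered, and 84% of those given 2, while 0.0558% of unchanged ones were called. On array B, of 11259 probe sets, these shares were 28%, 63% and 0.0452%. In a simulation with 2000 genes and 100 lists, the shifted list was called and no unshifted list was. Its genes were drawn independently, so it does not show how often lists of correlated genes are called falsely.

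Alternatives were a donor block, quantile normalization, floors at the 5th and 40th percentile, a pseudocount in place of the floor, no filter or a filter at the 75th percentile, array weights, no trend, adjustment over both array types, an estimated correlation between genes, the median over a gene's probe sets, and leaving out each donor pair or array. After the 3' to 5' ratios of the control transcripts GAPDH and ACTB had been seen, 4 were added: the class of this ratio as a block, the ratio as a covariate, and the comparison within the low-ratio and within the high-ratio samples.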

Results

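Transcript levels were measured in 2 kinds of myeloid cell sorted from the blood of 5 healthy donors. Myeloid dendritic cells (mDCs), which take up antigen and present it to T cells, were sorted as lineage-negative cells carrying CD11c and HLA-DR. Monocytes, circulating phagocytes, were sorted as cells carrying CD14 and HLA-DR. RNA of each cell type from each donor was hybridised to 2 complementary human arrays, called A and B, so that 20 arrays formed 4 groups of 5. Array A held 22283 probe sets and array B 22645. The median signal per array lay between 120.1 and 190.3 on array A and between 178.2 and 243.8 on array B, with each array scaled by the authors to 1 trimmed mean. The number of arrays limits the precision of every value. The comparison asked which transcripts distinguish blood mDCs from monocytes in healthy people. The monocytes of patients with lupus, which the study's design also names, were not analysed here.

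Blood mDCs and monocytes had separate transcript profiles. The first principal component, which took 38.9% of the variance on array A, placed the mDC arrays at 41.0 ± 7.58 and the monocyte arrays at -41.0 ± 9.59 (SD, n = 5 each; exact two-sided permutation p = 0.00794). On array B, where it took 27.5%, the means were 38.6 ± 7.96 and -38.6 ± 5.41 (SD, n = 5 each; exact two-sided permutation p = 0.00794). That p is the smallest that 252 free rearrangements of 10 arrays can give, and these take no account of the donors. Swaps of the cell types within the 5 donor pairs, a test added after the data were seen, gave an exact two-sided p = 0.0625 on both arrays, the smallest that 32 swaps can give, so that this permutation test cannot reach 0.05. The mean Spearman correlation across probe sets was 0.916 among mDC arrays, 0.883 among monocyte arrays and 0.820 between the cell types on array A. On array B these correlations were 0.827, 0.831 and 0.761.

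**Figure D1:**
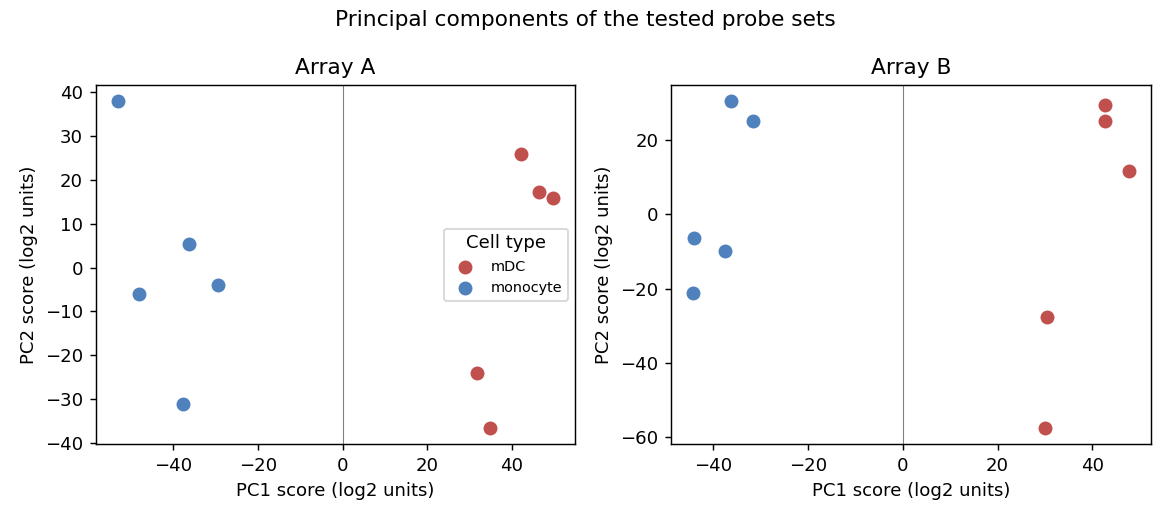
Scores of the 10 arrays of each array type on the first (x axis) and second (y axis) principal component of the tested probe sets, in log2 units, with 1 point per array and colour for cell type. The mDC arrays lie at 31.8 or above and the monocyte arrays at -29.4 or below on the first component of array A.

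On array A, 927 of 10953 tested probe sets were higher in mDCs and 815 were higher in monocytes at an adjusted p under 0.05, which is 15.9% of those tested. They stood for 686 and 590 genes. Of the called probe sets, 465 were at least 2-fold higher in mDCs and 507 at least 2-fold higher in monocytes, while 56 and 50 differed by at least 8-fold. The difference had the same sign in all 5 donor pairs for 897 of the 927 and 774 of the 815. Leaving out 1 donor pair gave 580 probe sets higher in mDCs, and leaving out another gave 590. Within the 5 samples with a low 3' to 5' ratio of control transcripts the counts were 491 and 444, and within the 5 with a high ratio they were 262 and 331.

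The genes with the largest rise in mDCs included surface receptors of blood dendritic cells. FCER1A, the IgE-binding chain of the high-affinity IgE receptor, was 75.2-fold higher in mDCs (log2 difference 6.23 ± 0.44, SE, n = 5 per cell type; adjusted p = 3.5e-07). CLEC10A, a lectin that binds galactose-type sugars, was 23.8-fold higher (4.57 ± 0.28). CD1C, which presents lipid antigens, was 22.6-fold higher (4.50 ± 0.24). CD2, an adhesion receptor best known from T cells, was 12.8-fold higher (3.67 ± 0.43), and CDH1, the adhesion protein E-cadherin, was 11.8-fold higher (3.56 ± 0.44). The amino acid transporter SLC38A1 had the largest difference of the named genes higher in mDCs on this array, 107-fold (6.74 ± 0.41, adjusted p = 1.12e-07). P2RY14, a receptor for UDP-sugars, was 48.0-fold higher (5.58 ± 0.40), and the orphan-type receptor GPR18 was 13.4-fold higher (3.74 ± 0.49). JCHAIN, which joins secreted IgM and IgA chains, was 33.5-fold higher (5.06 ± 0.68), with an SD of 1.84 among the mDC arrays. DEPTOR, an inhibitor of mTOR kinase, TMEM14A, the channel-like protein CLIC2, the replication-associated gene PCLAF, NDRG2 and the death receptor TNFRSF21 completed the 15 genes, with log2 differences from 4.45 for DEPTOR to 3.53 for TNFRSF21. With the median over its probe sets PCLAF was 1.56 in place of 3.65, still called. In monocytes 4 of 5 arrays lay at the floor for TMEM14A and CDH1, 3 of 5 for JCHAIN, DEPTOR and TNFRSF21, and 2 of 5 for SLC38A1, P2RY14, GPR18 and PCLAF, so that these folds and their order depend on the floor.

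The largest difference among the named genes higher in monocytes was that of CYP1B1, a cytochrome P450 enzyme, which was 108-fold higher in monocytes (log2 difference mDC minus monocyte -6.75 ± 0.50, SE, n = 5 per cell type; adjusted p = 4.9e-07). C5AR1, the receptor for complement fragment C5a, was 51.2-fold higher (-5.68 ± 0.37), with 4 of 5 mDC arrays at the floor value, as for MTARC1. CD14, the lipopolysaccharide co-receptor on which the monocytes were sorted, was 31.2-fold higher (-4.96 ± 0.27), which checks the labels. CRISPLD2 was 41.4-fold higher (-5.37 ± 0.36). VNN2, a membrane-anchored vanin, was 31.5-fold higher (-4.98 ± 0.32), and DYSF, the membrane repair protein dysferlin, 31.1-fold (-4.96 ± 0.30). AQP9, a water and glycerol channel, lay at the floor on all 5 mDC arrays and was at least 24.5-fold higher in monocytes (adjusted p = 7.35e-07). The scavenger receptor MARCO was 20.8-fold higher (-4.38 ± 0.40), the hexokinase HK3 20.6-fold (-4.36 ± 0.51) and DUSP6, a phosphatase of ERK kinases, 18.7-fold (-4.23 ± 0.32). MTARC1, the Wnt-secretion protein WLS, the growth factor NRG1, the heparan sulfate-cleaving enzyme HPSE and the sulfotransferase CHST15 had log2 differences from -5.21 for MTARC1 to -4.07 for CHST15. For WLS and NRG1 3 of 5 mDC arrays lay at the floor and for MARCO and HPSE 2 of 5, so that the folds of such genes and their order depend on the floor.

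**Figure D2:**
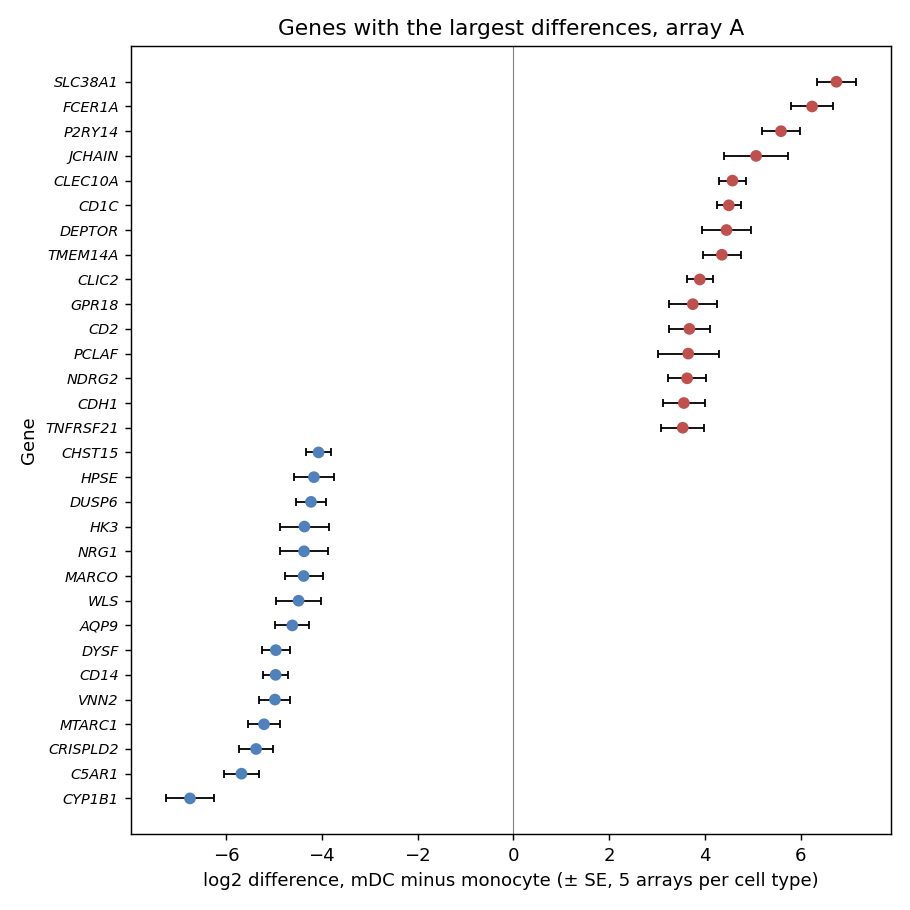
Log2 difference, mDC minus monocyte (x axis), of the 15 named genes with the largest difference in each direction on array A (y axis). Immunoglobulin segments are left out. Bars are 1 SE over 5 arrays per cell type. Red marks genes higher in mDCs and blue genes higher in monocytes. The points run from CYP1B1 at -6.75 to SLC38A1 at 6.74.

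On array B, 570 of 11259 tested probe sets were higher in mDCs and 534 higher in monocytes, 9.81% of those tested. They stood for 404 and 319 genes, and 368 and 349 of the probe sets differed by at least 2-fold. The sign was the same in all 5 donor pairs for 551 of the 570 and 515 of the 534. NFATC2, a transcription factor activated by calcineurin, was 107-fold higher in mDCs (log2 difference 6.74 ± 0.29, SE, n = 5 per cell type; adjusted p = 2.91e-10), and SLC38A1 was again high, 51.5-fold (5.69 ± 0.24). AFF3, the lysosomal channel MCOLN2, TENT5C, the magnesium transporter SLC41A2 and the epithelial-type factor EHF were 27.4-, 26.3-, 28.9-, 16.1- and 13.3-fold higher. TENT5C had an SD of 2.17 among the mDC arrays. With the median over its probe sets the log2 difference of AFF3 was 2.75 in place of 4.78. The probe set of the pseudogene HLA-DPB2 was 14-fold higher (3.81 ± 0.30), although near-identical HLA copies leave its source uncertain. RBP7, a retinol-binding protein, was 79.4-fold higher in monocytes (-6.31 ± 0.32, adjusted p = 2.18e-09), followed by GLT1D1 (74.7-fold) and the sphingosine phosphate receptor S1PR3 (48.5-fold). For GLT1D1 4 of 5 mDC arrays and for RBP7 and S1PR3 3 of 5 lay at the floor, so that these folds and their order depend on the floor. WLS (32.7-fold), LIN7A (29.9-fold), SASH1 (28.3-fold), the sialic acid lyase NPL (26.4-fold) and CLEC4E (22.4-fold), a receptor for mycobacterial glycolipid, were also higher in monocytes. For WLS, LIN7A and SASH1 2 of 5 mDC arrays lay at the floor, and for AFF3 2 of 5 monocyte arrays, so that their folds depend on it too. Leaving out 1 of 3 donor pairs gave 326, 356 or 374 probe sets higher in mDCs. Within the low-ratio samples 298 and 296 probe sets were higher in mDCs and monocytes, and within the high-ratio samples 113 and 174.

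Markers of conventional dendritic cells rose together in mDCs on array A. Of 18 measured members of the list of blood dendritic cell markers, 14 were higher in mDCs, none was higher in monocytes and 4 did not pass, with a median log2 difference of 2.02 (camera adjusted p = 2.66e-10). Adjusted over the list alone, 14 were higher in mDCs and 1, SIRPA (-0.67 ± 0.23), higher in monocytes. Beside FCER1A, CLEC10A and CD1C, NDRG2 was among the largest, 12.3-fold higher. ITGAX, which encodes the sort marker CD11c, differed by 0.11 ± 0.33 (SE, n = 5 per cell type; adjusted p = 0.866), with log2 signals of 9.87 ± 0.35 in mDCs and 9.76 ± 0.82 in monocytes (SD). On array B, 4 of 7 markers were higher in mDCs: SLAMF7, ZBTB46, WDFY4 and BTLA.

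Classical monocyte markers were higher in monocytes for 20 of 26 members and in mDCs for none, with a median log2 difference of -1.57 (camera adjusted p = 1.11e-18). Adjusted over the list alone the counts were 22 and none. Next to CD14, the calcium-binding alarmin S100A9 was 10.4-fold higher (-3.37 ± 0.24), the ectoenzyme BST1 9.17-fold (-3.20 ± 0.40) and the formyl peptide receptor FPR1 8.86-fold (-3.15 ± 0.33). LYZ (-0.41 ± 0.24) and CCR2 (-0.22 ± 0.21) were among the 6 that did not pass. On array B, 6 of 6 were higher in monocytes. Markers of non-classical monocytes were higher in monocytes for 7 of 14 members and in mDCs for 1, RHOC, with the same counts adjusted over the list alone (median -0.93, camera adjusted p = 7.64e-05). They included TCF7L2, a transcription factor of the Wnt pathway (-3.19 ± 0.27), MTSS1 (-2.37 ± 0.27), CTSL (-2.06 ± 0.37) and CDKN1C (-1.82 ± 0.49). The call of CDKN1C was lost without either of 2 donor pairs (adjusted p up to 0.0984). On array B, 1 of 4, MS4A7, was higher in monocytes. All 3 of these lists of dendritic cell and monocyte markers also passed with an estimated correlation between genes, at adjusted p = 0.00983, 0.00425 and 0.0232.

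Several markers of other blood cells moved with the mDC group. Of 12 measured markers of plasmacytoid dendritic cells (pDCs), which make type I interferon, 5 were higher in mDCs and none higher in monocytes (6 and none adjusted over the list alone; median 1.22, camera adjusted p = 0.00701). With an estimated correlation the adjusted p = 0.113, and within the high-ratio samples the median was 0.62 (adjusted p = 0.0990). The size of the pDC median rests on the members that passed the filter: without the filter it was 0.17 (adjusted p = 0.0117), and without 1 donor pair it was 0.81 (adjusted p = 0.0192). Those called were JCHAIN, ITM2C (2.56 ± 0.54), the transcription factors BCL11A (1.84 ± 0.22) and TCF4 (1.62 ± 0.32), and UGCG. PTCRA (0.07 ± 0.21), IRF7 (-0.43 ± 0.22) and PLAC8 (-0.33 ± 0.30) did not pass. On array B, BCL11A and UGCG of 4 markers were higher in mDCs. Of 4 B cell markers that passed the filter on low values, the signalling adaptors BLNK (3.06 ± 0.29) and BANK1 (2.80 ± 0.46) were higher in mDCs. The 2 others, CD79A (0.78 ± 0.51) and CD79B (0.80 ± 0.48), were not called, and the counts were the same adjusted over the list alone. Without the filter, only POU2AF1 was called of 11 B cell markers beside BLNK and BANK1. Of 3 progenitor markers that passed the filter, the receptor tyrosine kinase KIT (2.93 ± 0.47) and the ectoenzyme CD38 (1.85 ± 0.55) were higher in mDCs and CD34 (-0.03 ± 0.45) was not called. The monocyte means of BLNK, BANK1 and KIT (log2 signal 6.85, 6.86 and 5.53) lay below the filter level, so these genes passed it largely through the mDC arrays. The call of CD38 was lost without any 1 of 3 donor pairs (adjusted p up to 0.109), and without 1 of these its difference was 1.13.

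Among 27 immunoglobulin probe sets tested on array A, 13 were higher in mDCs and none higher in monocytes. These were examined after their values had been seen. Their mean log2 difference was 2.57 ± 0.64 (SE over 5 donor pairs), positive in 5 of 5 pairs, and the median SD among mDC arrays was 1.43 against 0.98 among monocyte arrays. The largest difference, of a probe set shared by several genes, was at least 7.54, since all its monocyte arrays lay at the floor. Among those with 1 gene symbol, a probe set annotated to the lambda gene IGLC1 differed most, by 6.95 ± 0.77, above the 6.74 of SLC38A1. Probe sets disagreed within genes: another of IGLC1 differed by 0.93 ± 0.79. For the heavy chain gene IGHM 1 differed by 3.63 ± 0.93 and another by -0.73 ± 0.85, and for the kappa gene IGKC 1 by 3.60 ± 0.69 and another by 0.82 ± 0.73. The lower value of each gene here came from a probe set designed for 1 transcript, and no probe set of that type was called. All 13 called were of types that can read related sequences, though others of these types were not called. Their signals can overlap, so the 13 are not separate readings. Without the filter on low values, POU2AF1, a member of both the B cell and the plasma cell list, was higher in mDCs (4.21 ± 0.71). The plasma cell marker TNFRSF17 was higher by at least 3.73, since its 5 monocyte arrays lay at the floor. No other of 13 plasma cell markers was called, among them XBP1 (0.09 ± 0.21) and SDC1 (-0.37 ± 0.69). Nor was any other of 11 B cell markers beside BLNK and BANK1, among them MS4A1 (-0.52 ± 0.55).

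**Figure D3:**
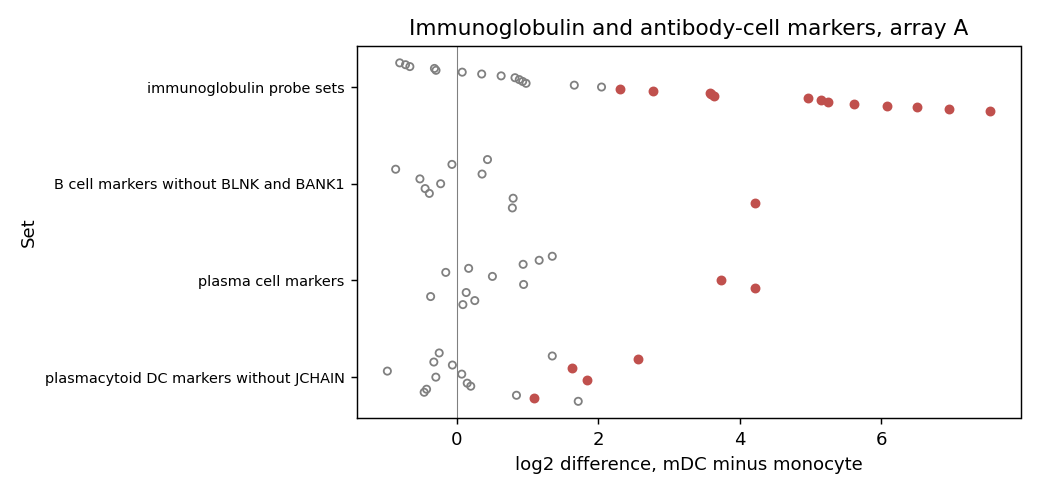
Log2 difference, mDC minus monocyte (x axis), on array A for immunoglobulin probe sets and for 3 marker lists (y axis), with 1 point per probe set or gene; filled red points passed an adjusted p of 0.05 and open points did not. Of 27 immunoglobulin probe sets 13 are filled, from the fit with the filter on low values. In the fit without that filter, 1 of 11 B cell, 2 of 13 plasma cell and 4 of 17 pDC markers are filled, so these shares are not directly comparable.

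Markers of lymphocytes, granulocytes and other blood cells were mostly below the filter or not different. Of 5 T cell markers, CD2 alone was called, and the list did not pass (camera adjusted p = 0.465, direction up); its median was -0.09 and its mean 0.71. Within the low-ratio samples the T cell list passed at adjusted p = 0.0225. Its median ran from -0.41 to 0.39 when a donor pair was left out and was 1.04 under quantile normalization. Neither of the 2 NK cell markers, none of 4 platelet markers and neither the erythroid marker HBB (-0.06 ± 0.23) nor the basophil marker GATA2 (-0.58 ± 0.41) passed. On array B the platelet marker MYL9 was higher in mDCs. Of 5 neutrophil markers, FCGR3B (-1.59 ± 0.34), an IgG receptor, and the granule enzyme MPO (-1.35 ± 0.44, adjusted p = 0.0495) were higher in monocytes. The call of MPO was lost without any 1 of 4 of the 5 donor pairs (adjusted p up to 0.172), with donor as a block (0.0522), under quantile normalization (0.0986) and without the filter on low values (0.0964). The neutrophil list did not pass (median -1.14, camera adjusted p = 0.126), except within the low-ratio samples (adjusted p = 0.0491). Its median was -0.61 without 1 donor pair and -0.16 without the filter on low values. On array B, CMTM2 was higher in monocytes. Counts adjusted over the list alone were the same for these lists.

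Genes of antigen presentation by MHC class II rose in mDCs. Of 16 measured members 11 were higher in mDCs and 1, the protease CTSS (-1.80 ± 0.25), was higher in monocytes (14 and 1 adjusted over the list alone; median 1.37, camera adjusted p = 6.55e-07, and adjusted p = 0.0232 with an estimated correlation). HLA-DOB, a regulator of peptide loading, was 9.73-fold higher (3.28 ± 0.44) and the endosomal protease LGMN 8.79-fold (3.14 ± 0.50), although 4 of 5 monocyte arrays had LGMN at the floor. HLA-DQB1 (2.66 ± 0.30) and CIITA, the master activator of these genes (2.27 ± 0.26), followed. With the median over its probe sets CIITA was 1.35, still called. HLA-DRA, whose product was used to sort both cell types, differed by 1.81 ± 0.36. HLA probe sets read related copies and donor sequence variants, so their values are less certain. On array B, HLA-DOA and HLA-DPB1 were higher in mDCs and CTSS higher in monocytes. Of 18 class I members 4 were higher in monocytes, HLA-E (-0.95 ± 0.18), HLA-F (-0.69 ± 0.20), HLA-B (-0.69 ± 0.21) and HLA-C (-0.63 ± 0.18), with the same counts adjusted over the list alone. The calls of HLA-B, HLA-C and HLA-F were lost without any 1 of 4, 3 and 4 donor pairs (adjusted p up to 0.152, 0.134 and 0.115). On array B, B2M of 6 members was higher in monocytes. The class I list did not pass (median -0.19, camera adjusted p = 0.136), but passed under quantile normalization (adjusted p = 0.0497). Its median ran from -0.28 to -0.06 when a donor pair was left out. Of 12 costimulation and maturation genes only LAMP3, a lysosomal protein of mature dendritic cells (1.80 ± 0.52), was called, also adjusted over the list alone, and the list did not pass (median 0.03, camera adjusted p = 0.597). The call of LAMP3 was lost without any 1 of 3 donor pairs (adjusted p up to 0.131). CD86 (-0.24 ± 0.28) and CD40 (-0.16 ± 0.32) were among those that did not pass.

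Of 22 pattern recognition receptors 10 were higher in monocytes and 1 in mDCs (12 and 1 adjusted over the list alone; median -0.73, camera adjusted p = 2.33e-06, and adjusted p = 0.00425 with an estimated correlation). CLEC4E (-2.46 ± 0.21) and TREM1, which amplifies inflammatory signals (-1.99 ± 0.28), stood beside CD14, whereas the mannose receptor MRC1 was higher in mDCs (3.03 ± 0.46). On array B, CLEC4E, TLR4, TLR8 and RIGI were higher in monocytes and TLR3 and TLR10 in mDCs, of 11 tested. Of 21 Fc, complement and scavenger receptors 11 were higher in monocytes, led by C5AR1 and MARCO, and 2, FCER1A and the TAM receptor kinase AXL (3.39 ± 0.40), were higher in mDCs. Adjusted over the list alone these counts were 12 and 2 (median -0.96, camera adjusted p = 2.99e-05, and adjusted p = 0.00748 with an estimated correlation). On array B, SCARB2, CD36 and CR1 were higher in monocytes. Paired immune receptors of the LILR and SIGLEC type were higher in monocytes for 10 of 17 members and in mDCs for none (13 and none adjusted over the list alone; median -0.97, camera adjusted p = 9.75e-07, and adjusted p = 0.00425 with an estimated correlation). LILRA3 (-2.89 ± 0.60), LAIR1 (-1.73 ± 0.24) and LILRB2 (-1.63 ± 0.30) were the largest beside TREM1. LILR genes resemble each other closely, so probe sets can share signal. On array B, HCST was higher in monocytes.

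Of 21 chemokine receptors and adhesion molecules 5 were higher in monocytes, including the integrin chain ITGAM (-2.97 ± 0.25), the chemokine receptor CCR1 (-2.31 ± 0.18) and PECAM1 (-1.51 ± 0.16), and the integrin chain ITGB7 (3.14 ± 0.31) was higher in mDCs. With the median over its probe sets ITGAM was -1.54, still called. Adjusted over the list alone 6 and 1 were called, and the list passed in the direction of monocytes (median -0.21, camera adjusted p = 0.0103). That call was lost with an estimated correlation (adjusted p = 0.10), without the filter on low values (adjusted p = 0.0705) and within the high-ratio samples (adjusted p = 0.149). Under quantile normalization the median was -0.32. On array B, S1PR3 and CD44 of 4 were higher in monocytes.

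Genes induced by interferon were higher in monocytes for 6 of 34 members and in mDCs for 1, LAMP3 (12 and 3 adjusted over the list alone; median -0.44, camera adjusted p = 0.00458), while its adjusted p = 0.301 with an estimated correlation. The chemokine CXCL10 (-1.85 ± 0.31), IFIT1 (-1.73 ± 0.32) and the ISG15 ligase HERC5 (-1.24 ± 0.28) were among those higher in monocytes, and MX1 (-0.24 ± 0.38) did not pass. LAMP3 lost its call without any 1 of 3 donor pairs (adjusted p up to 0.131). On array B, IFIT2, IFIT3 and RIGI of 14 were higher in monocytes. Inflammatory cytokines and chemokines were higher in monocytes for 5 of 14 members (7 adjusted over the list alone), with the interleukin IL18 (1.56 ± 0.23) higher in mDCs under both adjustments (median -0.68, camera adjusted p = 0.00359). The list's call was lost with an estimated correlation (adjusted p = 0.218) and within the high-ratio samples (median -0.32, adjusted p = 0.509). Its median was -1.13 within the low-ratio samples and -0.38 with the ratio as a covariate, and its mean difference differed between the ratio classes by 1.18 ± 0.36 (SE). The death ligand TNFSF10 (-2.21 ± 0.19) and the interleukin IL15 (-2.17 ± 0.27) were lower in mDCs of 5 of 5 pairs, and CXCL8 (-3.28 ± 0.96) and CXCL2 (-1.82 ± 0.58) in 4 of 5. The calls of CXCL8 and CXCL2 were lost without any 1 of 3 donor pairs (adjusted p up to 0.131 and 0.163). IL1B (0.02 ± 0.27) did not pass, and none of 4 members was called on array B.

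Immediate early and stress response genes were higher in monocytes for 10 of 27 members and in mDCs for 2, counts that were the same adjusted over the list alone (median -0.59, camera adjusted p = 2.24e-04, but adjusted p = 0.249 with an estimated correlation). DUSP6, the apoptosis regulator IER3 (-2.92 ± 0.37) and the transcription factor EGR1 (-2.63 ± 0.58) were higher in monocytes, whereas DDIT4, an inhibitor of mTOR signalling (2.98 ± 0.71), and the chaperone HSPH1 were higher in mDCs. Without the filter on low values EGR1 and DDIT4 lost their calls (adjusted p = 0.0529 and 0.0723). The list's median was -1.27 within the low-ratio samples (adjusted p = 4.54e-08) and -0.16 within the high-ratio samples (adjusted p = 0.476). On array B, KLF6, FOSL2 and EGR1 of 6 were higher in monocytes.

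Of 10 measured genes of S100, granule and antimicrobial proteins 3 were higher in monocytes and none in mDCs (4 and 1 adjusted over the list alone; median -0.52, camera adjusted p = 9.68e-04, but adjusted p = 0.106 with an estimated correlation). All 3 encode calcium-binding S100 proteins: S100A9, S100A12 (-2.96 ± 0.24) and S100A8 (-2.71 ± 0.23). Within the high-ratio samples the list's median was -0.34. On array B, S100A10 of 2 was higher in monocytes, whereas its array A probe set differed by 0.15 ± 0.15. LYZ and the ribonuclease RNASE2 (-0.68 ± 0.37) did not pass, and RNASE6 (0.86 ± 0.33) was called higher in mDCs over the list alone. Lysosomal proteases and membrane proteins were higher in monocytes for 12 of 26 members and in mDCs for 2, CST3 and ATP6V1H (13 and 2 adjusted over the list alone; median -0.63, camera adjusted p = 1.91e-05, and adjusted p = 0.0210 with an estimated correlation). The proteases CTSD (-2.66 ± 0.50), CTSL, CTSA (-1.96 ± 0.36) and CTSS had the largest differences. On array B, CTSB and CTSS of 8 were higher in monocytes and CST3 in mDCs.

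Myeloid transcription factors went both ways. Of 36 members 7 were higher in mDCs, including BATF3 (3.19 ± 0.39) and IRF4 (2.27 ± 0.30), which dendritic cell development needs, and ZEB1 (2.70 ± 0.49). A further 9 were higher in monocytes, including KLF2 (-2.62 ± 0.20), and the counts were the same adjusted over the list alone. The list as a whole did not pass (median -0.23, camera adjusted p = 0.301). Its median ran from -0.23 to -0.15 when a donor pair was left out. On array B, BCL11A, ZBTB46 and RUNX2 of 15 were higher in mDCs and KLF6, KLF2, BCL6, ZEB2, IRF1 and JDP2 higher in monocytes.

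**Figure D4:**
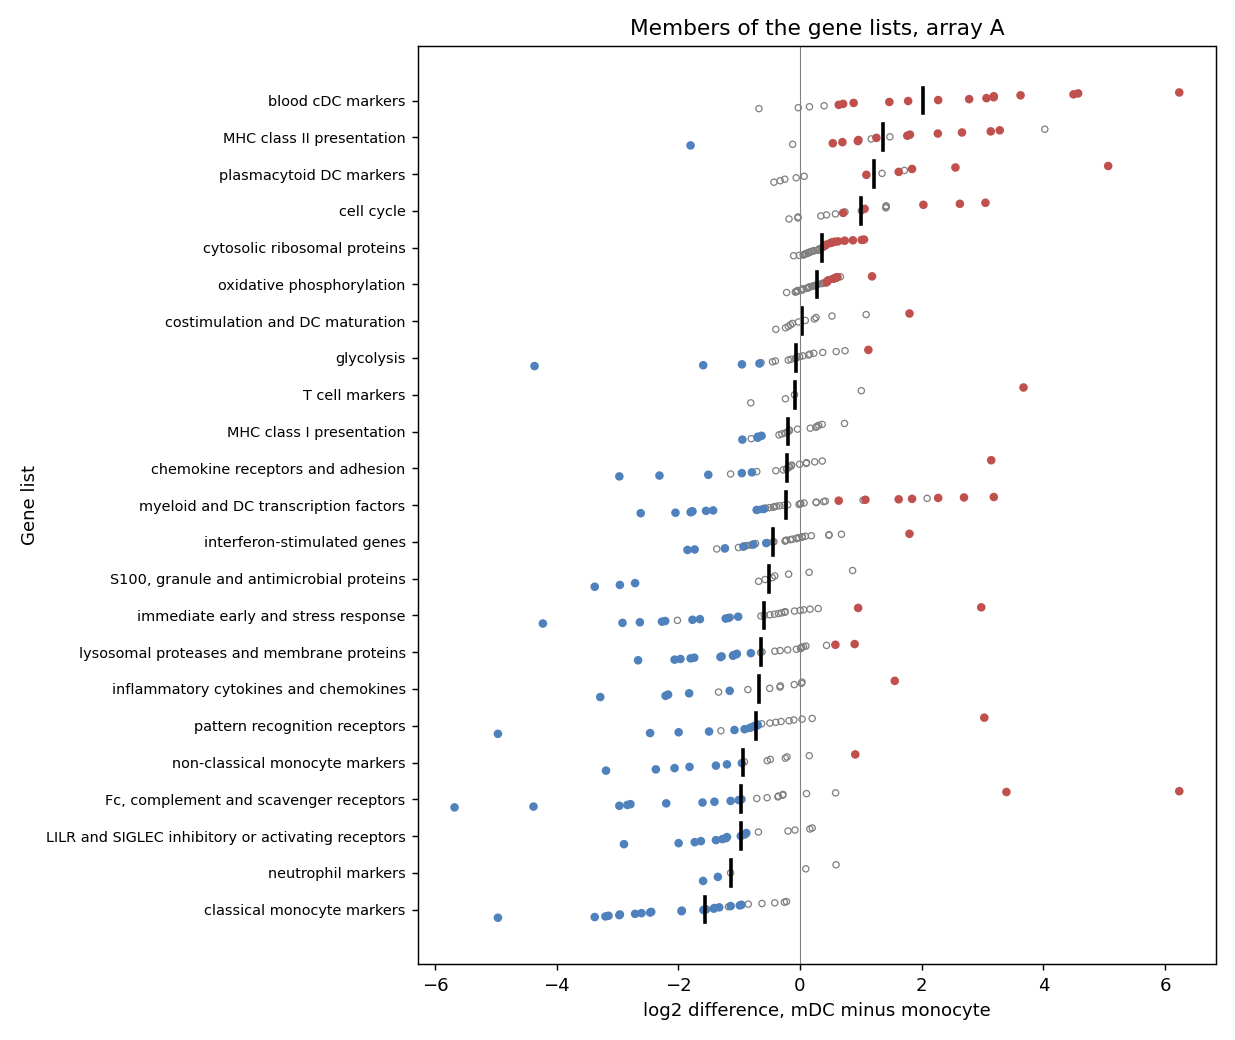
Log2 difference, mDC minus monocyte (x axis), of each measured member of the 23 tested gene lists (y axis) on array A, with 1 point per gene and a black bar at the list's median; red and blue points passed an adjusted p of 0.05 and open points did not. The medians run from -1.57 for classical monocyte markers to 2.02 for blood dendritic cell markers.

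Of 17 cell cycle genes 5 were higher in mDCs and none in monocytes (7 and none adjusted over the list alone; median 1.01, camera adjusted p = 1.56e-04). The list's call was lost with an estimated correlation (adjusted p = 0.10) and within the high-ratio samples (median 0.39, adjusted p = 0.0551). Its median was 1.36 within the low-ratio samples and 0.66 without 1 donor pair, and its mean difference differed between the ratio classes by -0.87 ± 0.27 (SE). The nucleotide synthesis enzymes TYMS (3.05 ± 0.48) and RRM2 (2.63 ± 0.74) and the replication helicase subunit MCM6 (2.03 ± 0.26) led them, with the spindle protein NUSAP1 (1.06 ± 0.22), and MKI67 (0.58 ± 0.47) did not pass. The call of RRM2 was lost without any 1 of 4 donor pairs (adjusted p up to 0.111). On array B, CCNB1 of 2 was higher in mDCs. Of 45 cytosolic ribosomal proteins 10 were higher in mDCs and none in monocytes (17 and none adjusted over the list alone; median 0.37, camera adjusted p = 1.66e-05, but adjusted p = 0.106 with an estimated correlation). RPL35 (1.05 ± 0.25), RPL3 (1.01 ± 0.26), RPS3 (0.87 ± 0.18) and RPS19 (0.74 ± 0.17) had the largest differences. The call of RPL3 was lost without either of 2 donor pairs (adjusted p up to 0.0940). On array B, 5 of 24 were higher in mDCs.

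Of 41 oxidative phosphorylation genes 8 were higher in mDCs and none in monocytes (10 and none adjusted over the list alone; median 0.28, camera adjusted p = 7.52e-04), a call lost with an estimated correlation (adjusted p = 0.10). Cytochrome c, encoded by CYCS, differed most (1.18 ± 0.19), and NDUFV1 (0.62 ± 0.19), ATP5F1A (0.59 ± 0.12) and COX5A (0.58 ± 0.17) by less. The calls of NDUFV1 and COX5A were lost without any 1 of 5 and 4 donor pairs (adjusted p up to 0.165 and 0.107). None of 7 members was called on array B. Of 20 glycolysis genes 4 were higher in monocytes, among them HK3, the glucose transporter SLC2A3 (-1.59 ± 0.46) and HK2 (-0.95 ± 0.24), and the lactate dehydrogenase chain LDHB (1.12 ± 0.28) was higher in mDCs (4 and 2 adjusted over the list alone). The calls of SLC2A3, HK2 and LDHB were lost without any 1 of 2, 2 and 1 donor pairs (adjusted p up to 0.124, 0.0849 and 0.0857). The glycolysis list did not pass (median -0.07, camera adjusted p = 0.320). Its median ran from -0.14 to -0.05 when a donor pair was left out and was -0.21 within the high-ratio samples, and on array B PFKFB4 of 3 was higher in monocytes. In all, 6 lists were higher in mDCs and 11 in monocytes of the 23 tested, and 2 and 6 with an estimated correlation. Some lists share members, so they are not separate findings. S100A8, S100A9, S100A12, CD14 and CLEC4E, for example, are classical monocyte markers that also stand in the S100 or the pattern recognition list.

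The array types gave similar differences for the same RNA. Across 100 probe sets present on both, Pearson's r of the log2 differences was 0.895 and Spearman's rho 0.884, and 10 were called on both, 10 of them in the same direction. Across 1846 genes read by different probe sets r was 0.613 and rho 0.508, and 108 of 108 genes called on both had the same direction, among them WLS, CLEC4E and SLC38A1. These are correlations across genes, which are not independent replicates.

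Control transcripts were read far more strongly at their 3' than at their 5' end. On array A the 3' to 5' signal ratio ran from 1.88 to 22 for GAPDH and from 12.2 to 61.3 for ACTB. The log2 ratio of ACTB was 4.47 ± 1.01 in mDCs and 5.11 ± 0.74 in monocytes (SD, n = 5 each; exact two-sided permutation p = 0.238, adjusted p = 0.524 over 4 tests), and that of GAPDH was 1.72 ± 0.49 and 2.24 ± 1.38 (exact permutation p = 0.571, adjusted p = 0.611). On array B the ACTB means were 4.44 ± 1.01 and 5.15 ± 0.98 (exact permutation p = 0.262, adjusted p = 0.524) and the GAPDH means 1.74 ± 0.62 and 2.16 ± 1.21 (exact permutation p = 0.611, adjusted p = 0.611). Swaps within donor pairs gave an exact p of 0.125 for ACTB on both arrays (adjusted p = 0.25), and of 0.5 and 0.375 for GAPDH (adjusted p = 0.5). The samples fell into 5 with mean log2 ratios from 2.34 to 2.84, of which 3 were mDC and 2 monocyte samples, and 5 with ratios from 3.79 to 5.26, of which 2 were mDC and 3 monocyte samples. Both samples of a donor mostly fell in the same class, so a difference between the classes may be a difference between donors.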

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

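The tests of other cell types, of RNA integrity and of scaling were chosen after the results had been seen, as were the counts of splits with an estimated correlation and of splits per list. The other counts of splits were set before the data were examined.

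Of 228 groups of 5 arrays, 20 held a sample whose gap to the nearest other exceeded 0.71 of the group's range, where chance gives about 1 in 20, or 11.4. In monocytes on array A, 1 sample stood above the others for TMEM14A (share of the range 1), CDH1 (1), LGMN (1), HPSE (0.931), S100A12 (0.806), BST1 (0.753), CTSL (0.750) and IRF4 (0.7105), and below them for CYP1B1 (0.772). In mDCs on array A, 1 sample stood above the others for C5AR1 (1), MTARC1 (1), WLS (0.827) and HK2 (0.748), and below them for CLEC10A (0.815) and BATF3 (0.771). On array B, 1 mDC sample stood above the others for GLT1D1 (1) and S1PR3 (0.933) and below them for CLEC4E (0.717). On array B, 1 monocyte sample stood below the others for NPL (0.7104) and above them for the GAPDH 3' to 5' ratio (0.723, a gap of 2.25). A share of 1 arises where the other 4 arrays lie at the floor.

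JCHAIN and 13 of 27 immunoglobulin probe sets were higher in mDCs (5 of the 27 were lower without passing, and no set test was run), and B cells, plasma cells or pDCs among the sorted cells could be a source, although the lineage-negative, CD11c-positive gate is meant to remove them. The marker lists were tested without the filter on low values, unlike the immunoglobulin probe sets. The called immunoglobulin probe sets were all of types that can read related sequences. B cell markers other than BLNK and BANK1 had a mean log2 difference of 0.369 ± 0.187 (SE over 5 donor pairs), with only POU2AF1 of 11 called. Their median was -0.07 and their mean was positive in 3 of 5 pairs, so the mean rests largely on POU2AF1 (4.21). Plasma cell markers had a mean of 0.995 ± 0.304 and a median of 0.50, with POU2AF1 and TNFRSF17 (whose monocyte arrays lay at the floor) of 13 called. XBP1 (0.09) and SSR4 (0.25) were not called. Both were bright in monocytes too (log2 signal 9.36 and 10.8), so a few plasma cells would hardly move them. The pDC markers other than JCHAIN, also without the filter, had a mean of 0.507 ± 0.142 and a median of 0.15, with 4 of 17 called. These values met the criterion first set for pDCs, at least 3 called and a mean above 0 by more than 2 SE. A condition that at least 1 of LILRA4, CLEC4C, IL3RA, GZMB and PTCRA be called was added after these values were seen, and LILRA4 (0.15), IL3RA (-0.46), GZMB (0.20) and PTCRA (0.07) were not called. These sources cannot be told apart from expression by mDCs, since dim markers lie near the floor, POU2AF1 is in 2 of the lists, and no biological explanation was tested.

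Ribosomal protein genes were higher in mDCs, and neither the 3' to 5' ratio nor array scaling accounted for the whole difference. That ratio only stands in for RNA integrity, and the extraction kit of each sample is not known, so other effects of RNA quality are not excluded. The list's median of 0.366 was at its smallest 0.288 across the fits with the 3' to 5' ratio class or the ratio as a term and within both classes, past the threshold in each. Under quantile normalization the median was 0.259 (adjusted p = 0.00264). The list's adjusted p = 0.106 with an estimated correlation, and 8 of 100 splits of the arrays gave a p as small, so chance is not excluded for it.

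Immediate early genes were lower in mDCs, and a difference in RNA integrity or handling may contribute. Their median was -0.59, -0.54 with the ratio class as a block and -0.41 with the ratio as a covariate, each past the threshold, but -0.160 within the high-ratio samples, where the call ended. The list's mean difference was -1.30 within the low-ratio and -0.157 within the high-ratio samples, a difference between classes of 1.14 ± 0.354 (SE). RNA integrity cannot be told apart from a difference between cell types or between donors here. Each class holds only 2 or 3 samples per cell type, and the samples of a donor mostly fell in the same class. The list's adjusted p = 0.249 with an estimated correlation, and 20 of 100 splits gave a p as small.

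More probe sets were called with the real split than with any other drawn split, though free splits take no account of the donor pairs. Every other split also mixes the cell types within its groups. The cell type difference then widens the spread in these splits, so that their low counts are partly built in. The real split gave 1742 calls on array A and 1104 on array B, and the highest of the other drawn splits gave 4 and 3, so that 1 of 100 was as large in both. At 2-fold or more the real counts were 972 and 717 and the highest others 4 and 3, again 1 of 100 each. Chance was not excluded for the count of 17 lists with the preset correlation, since 5 of 100 splits gave as many and the highest other gave 19. The median of the other splits was 5 lists. For single lists, the number of 100 splits with a p as small was 1 for blood dendritic cell, classical and non-classical monocyte markers, pattern recognition receptors and Fc receptors, 2 for the LILR list, and 3 for MHC class II and lysosomal genes. These numbers are not adjusted over the 23 tested lists, and a low one does not by itself exclude chance. Nor was chance excluded for chemokine receptors, S100 and cell cycle genes (6 each), pDC markers and ribosomal proteins (8 each), oxidative phosphorylation (10), cytokines (19), immediate early genes (20) and interferon-stimulated genes (29). A total of 8 lists passed with an estimated correlation. Of 100 splits, 1 gave as many, the real one, and the highest other gave 1, again without regard to the donor pairs. Of 11 other splits that part all 5 donor pairs, the highest gave no calls of probe sets and 17 lists with the preset correlation.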

How the results depend on the processing

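Of the counts and summary values under all alternatives, 264 were the same by the measure used (for counts, within 1.5 times) and 22 moved. Of single lists, genes and ratios, 1577 kept direction and side of the threshold, 86 lost their call, 3 gained one and 5 reversed. No called probe set changed sign in any setting run. The 4 alternatives on the 3' to 5' ratio were added after the data were seen.

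With the filter at the 75th percentile, which tests fewer probe sets, 282 and 311 on array A were at least 2-fold higher in mDCs and in monocytes, and 235 on array B in mDCs. Within the low-ratio samples, which are fewer, 491 and 444 were called on array A and 298 and 296 on array B. Within the high-ratio samples 262 and 331 were called on array A (243 and 313 at 2-fold) and 113 and 174 on array B (112 and 170 at 2-fold). In all, 2 lists were higher in mDCs and 6 in monocytes with an estimated correlation, and the cause was not tested. Leaving out a donor pair or array gave 580 to 1040 probe sets higher in mDCs on array A and 326 to 533 on array B. Reversals were of results without a call: within the high-ratio samples the test direction of T cell markers (median -0.553), costimulation (-0.218) and transcription factors (-0.0149), and without 1 donor pair costimulation (-0.0483; 0.142 without another) and ITGAX (-0.0195; 0.360 without another). The cause was not tested.

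A call was lost without 1 donor pair for 16 named genes, and for 18 when the donor block, the ratio class as a block, quantile normalization, the pseudocount, no filter and the median over probe sets are added. With the median over a gene's probe sets PCLAF fell to 1.56, AFF3 to 2.75, CIITA to 1.35, HLA-E was -0.62 and ITGAM -1.54, each still called. The other alternatives were not run for single genes. Of the 1742 probe sets called on array A, 824 were called within the low-ratio and 546 within the high-ratio samples, and of the 1104 on array B 531 and 266. With donor as a block 1252 and 1024 probe sets were called on array A and 680 and 638 on array B, and of the named genes and lists MPO alone lost its call. Without the filter the counts were 736 and 644, and 404 and 392. Dim transcripts near the floor limit what can be detected.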

Other observations

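The GIMAP and P2Y-like receptor families and the genes with opposed probe sets were chosen after their values were seen. GIMAP genes, which encode GTPases best known from lymphocytes, were higher in monocytes in all 7 measurements of 6 genes and in 5 of 5 donor pairs each. GIMAP8 (log2 difference -2.46 ± 0.19, SE, n = 5 per cell type), GIMAP1 (-2.37 ± 0.21) and GIMAP4 (-2.02 ± 0.25) had the largest differences. GIMAP6 was lower in mDCs on both arrays (-1.54 ± 0.20 and -1.84 ± 0.32).

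Receptors related to the P2Y family were split between the cell types. Of 10 genes, 5 were higher in mDCs: P2RY14, GPR18, GPR171 (3.36 ± 0.60), P2RY10 (3.11 ± 0.46) and GPR183, an oxysterol receptor (2.60 ± 0.64). Another 3 were higher in monocytes, GPR34 (-1.86 ± 0.57), LPAR6 (-1.41 ± 0.29) and P2RY13 (-1.19 ± 0.25), while P2RY12 (0.52 ± 0.65) and P2RY8 (-0.48 ± 0.20) did not pass.

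Of 213 genes with at least 2 called probe sets on array A, KDM2A alone had calls in both directions (0.65 ± 0.19 and -0.94 ± 0.26), and of 102 on array B, ANKRD28 alone did (2.07 ± 0.30 and -1.50 ± 0.35). None of 58 groups of genes sharing a symbol stem passed camera, with 6 at an unadjusted p under 0.05.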
